A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

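The samples were cultures of Saccharomyces cerevisiae BY4743, a diploid laboratory strain, in 3 groups of 3 arrays: vehicle control, HenGC-treated and SoyGC-treated. Per the labels and the series' design text, HenGC and SoyGC are GC preparations of hen of the woods, a mushroom, and of soybean, added at 40 ug/ml for 17 h before total RNA was taken. GC is not spelled out in the labels. In the sphingolipid field the letters usually stand for glucosylceramide, and the series' title speaks of a sphingolipid. No dose or time is given for the vehicle. The labels number the samples 1 to 3 within each group but do not say that they were separate cultures, so p-values measure only the spread between these samples, which may be technical.

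Per the labels' protocols, RNA was extracted with hot phenol and an RNeasy kit, and Cy3-labelled cRNA was made with Agilent's Quick Amp kit. Each sample was hybridised to one array of a slide design with 4 arrays, read in 1 colour. The submitters' processing notes name Agilent Feature Extraction 11.0.1.1 and R 3.0.2, and the role of R is not given in the sources used here. The deposited scanner files hold a linear fluorescence intensity per spot, the processed signal, which Feature Extraction had background-subtracted and detrended within the array, per the file headers. The files were not scaled between arrays. A deposited table of the authors' values was also read. Each of its values equalled, within a relative tolerance of 1e-06, the linear mean intensity of the 7 spots of a probe, for 100% of the values on each array, so its scale is linear and it is neither centred nor scaled. The medians of its columns were 2322, 2105 and 2009 for vehicle 1 to 3, 1772, 1799 and 2634 for HenGC 1 to 3, and 1772, 2177 and 2504 for SoyGC 1 to 3. This table served as an alternative only.

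Each array held 43792 spots that were not controls, 7 for each of 6256 probes. Arrays were assigned to slides by the barcode recorded with each file and to scan days by the scan times in the headers. Slide 1 held vehicle 1 and 2 with SoyGC 1 and 2, slide 2 held HenGC 1 and 2, and slide 3 held replicate 3 of every group. Slides 1 and 2 were scanned on scan day 1 and slide 3 on scan day 2.

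The log2 of the processed signal was taken, and each array's 75th percentile over non-control spots was subtracted. Control spots and spots that the software marked as outliers were left out, and the remaining spots of a probe were averaged. A probe counted as well above background on an array where over 50% of its spots were so marked. Probes well above background on all 3 arrays of at least 1 group were tested, and a gene with several such probes was represented by the brightest over the 9 arrays. Names came from the systematic names in the files, matched to a gene table of assembly R64 used for names only, since the headers name an older build. Of 6256 probes, 5765 matched, 462 carried an open reading frame name that the table lacks and kept the file's name, and 29 had no gene name that was used. The array covered 6199 genes, and 5814 genes were tested, 254 of them absent from the table. For 25 genes more than 1 probe was tested.

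A linear model with a mean for each of the 3 groups was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, and limma's moderated statistics were computed with eBayes. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the genes tested were called past the threshold. limma's F-test gave genes that differed among the 3 groups in any way. Fold changes are differences of group means on the log2 scale with their standard errors (SE), and levels are log2 values relative to the 75th percentile with the standard deviation (SD) over 3 arrays. A gene that was not well above background on any array of a group has only a bound there. Its fold is given as at least the brighter group's mean against the mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

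Gene groups were 34 lists of yeast genes. They were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and adjusted over the 34 lists of a comparison. camera was repeated with the correlation estimated from the data, and no list passed in any comparison with that setting, so its adjusted p stands beside each list that passed at the preset correlation. It was also run with each array left out. limma's fry was run too: its one-way p asks whether a list's genes move on balance in one direction, its mixed p whether they change in either direction, and neither compares a list with other genes. The 95% confidence interval of a list comes from the same kind of linear model on the list's mean per array. Counts of members past the threshold are given over all genes and adjusted over the list alone. The symbols FEN1, ARG5,6, DUR1,2 and FRDS1 of the lists matched no gene, 4 names in all. Some lists share members. HSP26 is in the general stress and Hsf1 lists, and CYC7 in the respiratory chain and anaerobic lists. AUS1 and PDR11 are in the drug resistance and anaerobic lists. Calls of such lists are therefore not independent of each other.

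Genes named in the text were taken by rule: for each comparison the 12 highest and the 12 lowest fold changes among genes past the threshold whose arrays of one group all lay above or all below those of the other, the 3 smallest p-values per direction where none passed, and 2 to 4 members per list with the smallest p. Other genes named were chosen after their values were seen, and the text says so. HIS3, LEU2 and URA3 were read as a check of the strain. The comparisons, the lists, the rule and most alternatives were fixed before the data were examined. Alternatives using the scan day or leaving out vehicle 3 from the list counts, and lists with an estimated correlation and an array left out, were chosen after seeing the data, as were the simulated overlap and signs of the comparisons.

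The fit and the list test were tested on simulated arrays with the spread of these data and 200 changed genes among 5814 in each of 10 runs. For HenGC against vehicle, 50.1% of genes changed 1.5-fold, 83.1% of those changed 2-fold and 96.4% of those changed 4-fold were recovered. For SoyGC against vehicle the shares were 48.7%, 84.8% and 96.8%, and for HenGC against SoyGC 51.9%, 77.3% and 96.8%. False calls made up 5.61%, 5.99% and 5.21% of the calls. A list shifted by 0.3 on the log2 scale was called in 10 of 10 runs of each comparison, and of 330 tests of other lists 1, 0 and 1 were called. Simulated genes varied independently, so this says nothing of lists whose genes vary together. Each simulated gene had the same spread on all arrays, so the shares leave out the wider spread of the vehicle arrays. The root mean square SD was 0.338 in vehicle, 0.188 in HenGC and 0.219 in SoyGC. The number of arrays limits the precision: the median gene had an SE of 0.13 and a 95% interval reaching 0.30 to either side.

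Most alternatives changed 1 choice at a time: normexp background correction (offset 50), quantile or median scaling, the authors' deposited table, the filter on dim probes, the mean of a gene's probes, slide, scan day or replicate number as a block, only the groups compared, a robust prior with a trend, array weights, and each array left out in turn. Normexp was planned on mean signals, which are not given in the sources used here, and was run on median signals, so it changed the signal as well as the background correction. The authors' table differs in scaling, in averaging spots before the log and in keeping outlier spots. Files were read with data.table (1.17.8) and jsonlite (2.0.0), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.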

Results

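Gene expression was measured in yeast given a vehicle, HenGC or SoyGC, each on 3 arrays. Signal was high on every array: 92.4% to 95.8% of the 43792 spots lay well above background, the 75th percentile of the signal ranged from 5273 to 7803, and 0 spots were saturated. Spots that the software marked as outliers made up 0.527% to 1.17%, and the median variation among the 7 spots of a probe was 3.97% to 4.37%. HIS3, LEU2 and URA3, marker genes that this strain background lacks in whole or part, were well above background on 0 of 9 arrays.

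Arrays of a group correlated across genes at 0.998 for vehicle 1 and 2, 0.994 to 0.995 for HenGC and 0.991 to 0.995 for SoyGC, while vehicle 3 correlated with the other vehicle arrays at 0.977 and 0.979. Genes are not independent replicates, so these values describe the arrays only. Vehicle 3 differed over 2-fold from the mean of vehicle 1 and 2 at 515 genes, 503 of them lower. HenGC and SoyGC arrays differed over 2-fold from the mean of their own group mates at 16 to 60 genes. Vehicle 1 and 2 did so at 114 and 49 genes, against means that include vehicle 3. From each other vehicle 1 and 2 differed over 2-fold at 0 genes. The first principal component, with 56.3% of the variance, placed vehicle 3 at -41.7 and the other 8 arrays between -3.64 and 14.6. No pair of arrays within a group was alike to the error of its spots: their differences were at least 3.78 times that error. The ribosome biogenesis list had the lowest mean in vehicle 3 relative to vehicle 1 and 2, at -0.74 on the log2 scale, so counts of list members without vehicle 3 are given where it moves them by over 1.5 times.

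The first comparison asked which genes differed between HenGC-treated and vehicle-treated cells. The maltases MAL12 and MAL32 rose 3.17-fold and 3.03-fold (log2 1.66 ± 0.18 and 1.60 ± 0.18, SE, n = 3 per group), and the maltose permease gene MAL31 rose by 1.31 ± 0.20. MAL12 stood at -3.61 ± 0.26 (SD) in HenGC and -5.28 ± 0.10 in vehicle, and since the MAL12 and MAL32 sequences are nearly identical, their signals cannot be assigned with certainty. STR3, a cystathionine beta-lyase, rose 2.22-fold (1.15 ± 0.10), and HSP12, a small membrane-associated stress protein, rose 3.02-fold (1.60 ± 0.30). The protein kinase gene RCK1 fell by 1.49 ± 0.22, the alpha-factor gene MF(ALPHA)2 by 1.15 ± 0.12 and the ammonium permease gene MEP1 by 1.01 ± 0.16. In limma's test the adjusted p was 0.0072 for MAL12, 0.00836 for MAL32, 0.0275 for MAL31, 0.00648 for STR3, 0.0477 for HSP12, 0.0256 for RCK1, 0.0072 for MF(ALPHA)2 and 0.0275 for MEP1. HSP12 was -0.82 in vehicle 3 relative to vehicle 1 and 2, and without vehicle 3 its difference was 1.32 with an adjusted p of 0.0633. Over the alternatives its adjusted p ranged from 0.0027 to 0.436.

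Other genes that rose were FMP16 (1.3 ± 0.12), YMR206W (1.29 ± 0.13), CSR2 (1.29 ± 0.19), RTN2, a reticulon-like protein (1.16 ± 0.17), YML089C (1.14 ± 0.14), EDS1 (1.11 ± 0.19) and SOL4, a 6-phosphogluconolactonase (1.1 ± 0.14). Genes that fell were YOR387C (-0.87 ± 0.13), the peptide transporter PTR2 (-0.77 ± 0.14), the S-phase cyclin CLB6 (-0.74 ± 0.11), YER158C (-0.72 ± 0.12), the peroxisomal citrate synthase CIT2 (-0.70 ± 0.13), MF(ALPHA)1 (-0.70 ± 0.12), VEL1 (-0.69 ± 0.13), RTS3 (-0.60 ± 0.11) and the forkhead factor HCM1 (-0.59 ± 0.11). Without vehicle 3, PTR2, YER158C, CIT2, MF(ALPHA)1, VEL1, RTS3 and HCM1 no longer passed, with adjusted p of 0.0541, 0.0541, 0.0864, 0.0633, 0.0541, 0.0753 and 0.0724. The adjusted p of these 7 genes ranged over the alternatives from 0.00148 to 0.535.

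In total 69 of 5814 genes passed in limma's test, 53 higher and 16 lower, and 18 of them by at least 2-fold. The split depended on the setting: 33 higher and 6 lower after quantile normalization, 3 and 0 in the authors' table, 74 and 51 with scan day as a block, and 418 and 444 with array weights. At an unadjusted p under 0.05, 495 genes were higher and 747 lower. The groups did not overlap at 1742 genes, or 29.96%, where chance gives 10%, and at all 69 genes that passed. Their median size was 0.80 within scan day 1 and 0.75 within scan day 2, while the direction within a day is fixed where groups do not overlap and tests nothing. On scan day 1 the HenGC arrays lay on slide 2 and the vehicle and SoyGC arrays on slide 1. A slide effect may thus stay in the scan day 1 values of HenGC against vehicle or SoyGC. With scan day as a block, which does not remove that difference between slides, 125 genes passed. With slide as a fixed block 0 passed and 477 had an unadjusted p under 0.05. Slide 2 held HenGC arrays alone, so in that fit HenGC 3 is the 1 array that stands for HenGC. With slide as a random block 64 passed. The count rested on single arrays: it was 16 without vehicle 1, 3 without vehicle 2, 5, 9 and 23 without HenGC 1, 2 and 3, and 34, 35 and 25 without SoyGC 1, 2 and 3. Without vehicle 3 it was 50, of which 41 were among the 69.

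**Figure D1:**
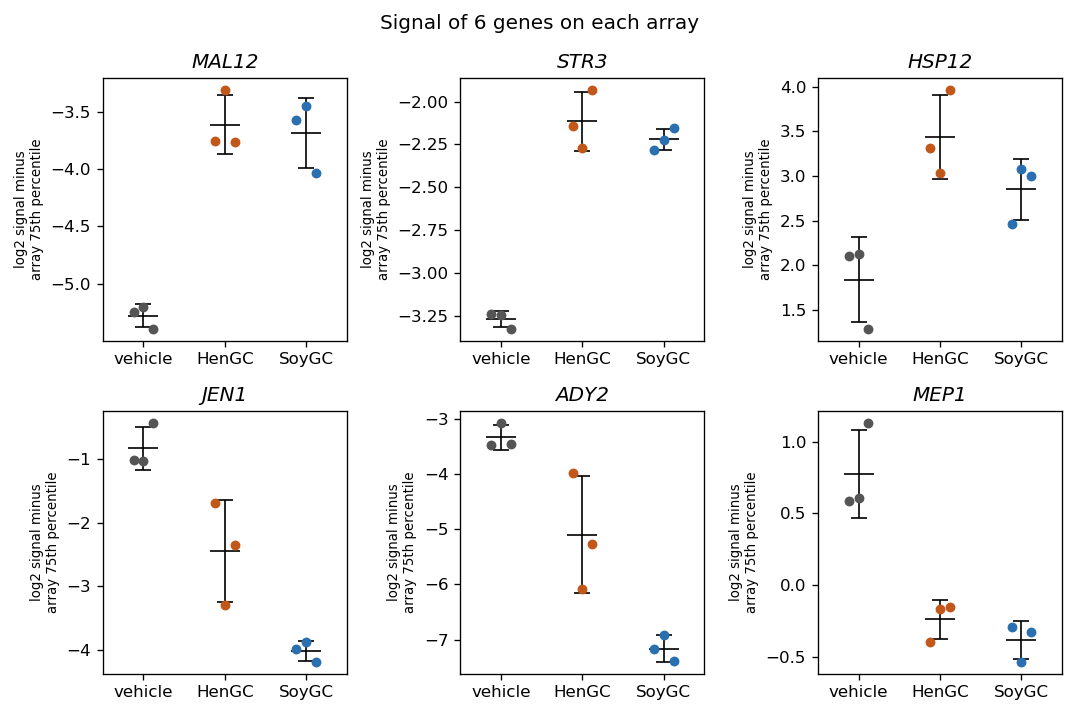
Levels of MAL12, STR3, HSP12, JEN1, ADY2 and MEP1 (log2 signal relative to the array's 75th percentile) in vehicle, HenGC and SoyGC arrays, where points are the 3 arrays of a group and bars show the mean and SD. MAL12 stood at -5.28 in vehicle, -3.61 in HenGC and -3.69 in SoyGC.

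Among gene groups, 9 of 43 measured genes of the general stress response under Msn2 and Msn4 rose and 0 fell in HenGC, among them the mitochondrial outer membrane protein OM45 (0.81 ± 0.09), SOL4, NQM1 (0.68 ± 0.09) and MSC1 (0.81 ± 0.12). Adjusted over the list alone 23 rose and 3 fell. The list's mean difference was 0.43 (95% interval 0.27 to 0.59), with a camera adjusted p of 9.1e-09 and an adjusted p = 0.216 with an estimated correlation. Its mean was 0.38 within scan day 1 and 0.54 within scan day 2. Without vehicle 3, 8 rose.

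The list of nitrogen catabolite repression and permeases had 32 measured genes, among them permeases for ammonium, amino acids and peptides. Of these 32 genes MEP1 and PTR2 fell, 14 fell adjusted over the list alone, and 29 had negative differences. The mean was -0.40 (95% interval -0.60 to -0.20; camera adjusted p = 2.3e-08, adjusted p = 0.216 with an estimated correlation), and -0.41 and -0.39 within the scan days. Without vehicle 3, 1 gene fell.

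The list of sphingolipid synthesis and turnover, the lipid class that the series is about, had 1 of 36 genes past the threshold. This was the alkaline ceramidase YPC1, which rose by 0.82 ± 0.16 (adjusted p = 0.0495) and was the 1 gene that passed when adjusted over the list alone. The list's mean was -0.12 (95% interval -0.21 to -0.03), with 29 negative members, a camera adjusted p of 0.00578 and an adjusted p = 0.392 with an estimated correlation. ORM1 and LAC1 had values of -0.35 ± 0.10 and -0.33 ± 0.10 and did not pass. The mean was -0.098 in scan day 1 and -0.17 in scan day 2, vehicle 3 was 0.12 on this list relative to vehicle 1 and 2, and without it 0 genes passed and YPC1 had an adjusted p of 0.0619, in a range of 0.00148 to 0.535 over the alternatives.

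Ribosome biogenesis had positive differences at 90 of 95 genes, although 0 passed over all genes and 0 adjusted over the list alone. IMP4, of the small subunit processome, was at 0.59 ± 0.13 (adjusted p = 0.0639). The mean was 0.52 (95% interval -0.07 to 1.12), with a camera adjusted p of 2.5e-14, an adjusted p = 0.392 with an estimated correlation, and within-day means of 0.28 and 1.01. Mitochondrial ribosomal proteins were positive at 65 of 69 genes with 0 past the threshold over all genes and 0 adjusted over the list alone (mean 0.29; camera adjusted p = 1.3e-09, adjusted p = 0.216 with an estimated correlation). Vehicle 3 lay at -0.74 and -0.30 on these lists relative to vehicle 1 and 2, and without it the means were 0.28 and 0.19.

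Among 43 genes of the respiratory chain, the cytochrome c isoform CYC7 (1.07 ± 0.15) and the lactate dehydrogenase CYB2 (0.94 ± 0.16) rose, and 4 rose adjusted over the list alone (mean 0.30; camera adjusted p = 6.8e-07, adjusted p = 0.318 with an estimated correlation). Of 33 protein folding genes under Hsf1, HSP26 rose (0.65 ± 0.12) and 2 rose adjusted over the list alone (mean 0.28; camera adjusted p = 0.000283, adjusted p = 0.318 with an estimated correlation), with vehicle 3 at -0.33 and a mean of 0.18 without it. Of 35 oxidative stress genes under Yap1, PRX1, MXR1 and OYE3 rose (0.65 ± 0.11, 0.68 ± 0.12 and 0.80 ± 0.15), 3 also when adjusted over the list alone (mean 0.18; camera adjusted p = 0.0282, adjusted p = 0.462 with an estimated correlation). Without vehicle 3, 1 Yap1 gene rose, and without HenGC 1 the list's mean was 0.11.

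Several lists were lower in HenGC with few genes past the threshold. Of 39 genes of G1/S, CLB6 fell and 11 fell adjusted over the list alone (mean -0.17; camera adjusted p = 0.000427, adjusted p = 0.261 with an estimated correlation). Of 29 haploid-specific genes, MF(ALPHA)1 and MF(ALPHA)2 fell and 6 fell adjusted over the list alone (mean -0.23; camera adjusted p = 0.00198, adjusted p = 0.216 with an estimated correlation). Without vehicle 3, 1 fell. These are genes that haploid cells use for mating, and the strain is diploid. Cell wall genes had 0 of 32 past the threshold and 7 lower adjusted over the list alone, with PST1 at -0.62 ± 0.13 (mean -0.18; camera adjusted p = 0.000103, adjusted p = 0.318 with an estimated correlation). The phosphate regulon (24 genes, mean -0.20), ergosterol synthesis (28 genes, -0.14), thiamine metabolism (21 genes, -0.15), G2/M (34 genes, -0.075) and the fusel alcohol list (28 genes, -0.12) each had 0 genes past the threshold. Adjusted over the list alone, 0, 0, 1, 4 and 0 of their genes fell. Their camera adjusted p was 0.000707, 0.00908, 0.0185, 0.0282 and 0.0452, and their adjusted p = 0.347, 0.514, 0.318, 0.392 and 0.433 with an estimated correlation. The G2/M list was -0.12 in scan day 1 and 0.015 in scan day 2, and -0.028 without vehicle 1 and -0.14 without vehicle 3.

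Of 34 lists, 16 passed camera in this comparison, 6 upward and 10 downward, and 0 passed with an estimated correlation. fry called 12 lists as moving one way on balance and 23 as changing in either direction. Within both scan days 15 of the 16 kept their sign, G2/M being the exception, and 16 were called with scan day as a block. The days split the values that gave the calls, and most lists not called kept their sign too. Kept signs therefore test little. Without vehicle 3 the calls of thiamine metabolism and the fusel alcohol list were lost, the latter also without vehicle 2 or HenGC 3. Quantile normalization ended the ergosterol and fusel alcohol calls, the normexp fit on median signals that of haploid-specific genes, and scan day 1 alone those of thiamine metabolism and the fusel alcohol list. The fusel alcohol call was also lost with array weights and without the dim filter. Ergosterol synthesis, Yap1, the fusel alcohol list and G2/M were not called with slide as a fixed block. Leaving out vehicle 1, vehicle 2 or HenGC 1 also ended the Yap1 call, and leaving out vehicle 1, vehicle 2, HenGC 2 or HenGC 3 the G2/M call. Of 1218 genes in the lists 28 passed, and this count was 6, 1 and 17 without vehicle 1, 2 and 3, 2, 3 and 7 without HenGC 1, 2 and 3, and 14, 15 and 10 without SoyGC 1, 2 and 3.

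The second comparison asked the same of SoyGC. The acetate transporter gene ADY2 fell 14.2-fold (log2 -3.82 ± 0.43, SE, n = 3 per group), the lactate and pyruvate permease gene JEN1 9.18-fold (-3.20 ± 0.35), and RGI2, a gene of respiratory growth, 14.9-fold (-3.90 ± 0.56). POT1, the thiolase of peroxisomal fatty acid oxidation, fell 4.19-fold (-2.07 ± 0.34), and the sterol uptake transporters PDR11 and AUS1 fell 3.53-fold and 3.37-fold (-1.82 ± 0.40 and -1.75 ± 0.46). MAL12 and MAL32 rose 3.01-fold and 2.80-fold (1.59 ± 0.18 and 1.48 ± 0.18). Genes of ribosome synthesis rose, among them RRP14 (2.00 ± 0.46), CGR1 (1.77 ± 0.46) and DHR2 (1.3 ± 0.16), as did the glutathione peroxidase gene GPX2 (2.00 ± 0.45). In limma's test the adjusted p was 0.00914 for ADY2, JEN1 and MAL12, 0.0149 for RGI2, 0.0212 for POT1, 0.0349 for PDR11, 0.0484 for AUS1, 0.0114 for MAL32, 0.0381 for RRP14, 0.0465 for CGR1, 0.0123 for DHR2 and 0.0362 for GPX2. JEN1 stood at -4.02 ± 0.15 (SD) in SoyGC against -0.82 ± 0.34 in vehicle, and ADY2 at -7.16 ± 0.24 against -3.34 ± 0.22. ADY2, JEN1, RGI2 and POT1 also lay below vehicle in HenGC, by less than in SoyGC, and did not pass there. Vehicle 3 lay at -1.37 for RRP14 and -1.67 for CGR1 relative to vehicle 1 and 2. Without it, RRP14, CGR1, GPX2, PDR11 and AUS1 had adjusted p of 0.0642, 0.0595, 0.0702, 0.068 and 0.104, and over the alternatives these 5 genes ranged from 0.0123 to 0.205.

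Further genes that rose were BUD22 (1.36 ± 0.33), DRS1 (1.26 ± 0.34), RRP1 (1.18 ± 0.24) and REX4 (1.14 ± 0.29), all of ribosome synthesis, with YLR108C (1.17 ± 0.29) and YOR186W (1.15 ± 0.13). Further genes that fell were PBI1 (-2.17 ± 0.50), RCK1 (-1.83 ± 0.22), IZH4 (-1.78 ± 0.46), FHN1 (-1.77 ± 0.44) and YML083C (-1.66 ± 0.34). YOR008C-A was not well above background on any SoyGC array and was at least 1.45-fold lower (adjusted p = 0.0296). Without vehicle 3, BUD22, DRS1, REX4, YLR108C, PBI1, IZH4, FHN1, YML083C and YOR008C-A had adjusted p of 0.0659, 0.0522, 0.0515, 0.0671, 0.0751, 0.0857, 0.0858, 0.0584 and 0.0561, and over the alternatives these 9 genes ranged from 0.00501 to 0.229.

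In total 539 of 5814 genes passed in limma's test, 194 higher and 345 lower, and 58 by at least 2-fold, 21 higher and 37 lower. After quantile normalization the split was 187 higher and 202 lower. In the authors' deposited table, which is not scaled between arrays, 8 genes passed, 2 higher and 6 lower. The groups did not overlap at 1987 genes, or 34.2%, where chance gives 10%. These include all 539 that passed, so their direction within a scan day is fixed and tests nothing. The median size was 0.52 within scan day 1, which for these groups is slide 1, and 0.83 within scan day 2. With scan day as a block 747 genes passed, with slide as a fixed block 188, with slide as a random block 638 and within slide 1 alone 39. The count was 22 without vehicle 2, 171 without vehicle 3, 320, 281 and 289 without HenGC 1, 2 and 3, and 39, 49 and 2 without SoyGC 1, 2 and 3. Of the 171 genes without vehicle 3, 166 were among the 539.

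Ribosome biogenesis was higher in SoyGC: 36 of 95 genes rose and 0 fell, 82 rose adjusted over the list alone, and 94 had positive differences. IMP4 rose by 0.93 ± 0.13, YTM1 by 0.89 ± 0.13, ENP1 by 0.71 ± 0.12 and TSR1 by 0.69 ± 0.11. The mean was 0.80 (95% interval 0.21 to 1.40; camera adjusted p = 1.9e-29, adjusted p = 0.252 with an estimated correlation), and 0.46 and 1.5 within the scan days. With vehicle 3 at -0.74 on this list, 14 genes rose without that array and the mean was 0.56. Of 137 genes under the heading of cytosolic ribosomal proteins 2 rose, 1 adjusted over the list alone. They were RPL35B (0.32 ± 0.08) and RPP1 (0.59 ± 0.09), which encodes a subunit of RNase P and is no ribosomal protein (list mean 0.15; camera adjusted p = 4.7e-07, adjusted p = 0.458 with an estimated correlation), and 1 rose without vehicle 3. Of 69 mitochondrial ribosomal genes, MRPL38 and MRPL27 rose (0.41 ± 0.08 and 0.56 ± 0.15), and 0 adjusted over the list alone (mean 0.27; camera adjusted p = 9.6e-10, adjusted p = 0.252 with an estimated correlation). Vehicle 3 was at -0.30 on that list, and without it 0 genes rose and the mean was 0.17.

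Genes in the list of nitrogen catabolite repression and permeases were lower: 14 of 32 fell, 22 adjusted over the list alone. Among them were MEP1 (-1.15 ± 0.16), the amino acid permease genes DIP5 (-1.05 ± 0.16) and CAN1 (-0.73 ± 0.12), and PTR2 (-0.86 ± 0.14). The list mixes both kinds of gene, so its fall cannot be credited to catabolite repression alone. The mean was -0.62 (95% interval -0.83 to -0.42; camera adjusted p = 2.3e-10, adjusted p = 0.252 with an estimated correlation), and -0.53 and -0.81 within the scan days. Without vehicle 3, 8 fell.

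In the tricarboxylic acid and glyoxylate cycle list, which includes transporters of its substrates, 6 of 31 genes fell, and 8 adjusted over the list alone. JEN1, ADY2, the acetyl-CoA synthetase ACS1 (-0.83 ± 0.11) and CIT2 (-0.78 ± 0.13) led them. The median was -0.20 and the mean -0.51 (95% interval -0.69 to -0.33; camera adjusted p = 0.000286, adjusted p = 0.252 with an estimated correlation), with -0.43 and -0.67 within the scan days. Without vehicle 3, which lay at 0.11 on this list, 4 fell. Of 29 glycolysis and fermentation genes 5 fell, also 5 adjusted over the list alone, including the glycerol-3-phosphate dehydrogenase GPD1 (-0.71 ± 0.12) and the phosphofructokinase subunits PFK1 (-0.49 ± 0.11) and PFK2 (-0.68 ± 0.13). Their mean was -0.24 (camera adjusted p = 0.000533, adjusted p = 0.458 with an estimated correlation), vehicle 3 lay at 0.14, and 1 fell without it. Of 21 trehalose and glycogen genes 4 fell, and 6 adjusted over the list alone, among them GAC1 (-0.68 ± 0.13), TPS1 (-0.65 ± 0.15) and TPS2 (-0.56 ± 0.13). Their mean was -0.23 (camera adjusted p = 0.00242, adjusted p = 0.458 with an estimated correlation), and 1 fell without vehicle 3. In the respiratory chain list CYC7 rose (0.68 ± 0.15) and the succinate dehydrogenase subunits SDH3 and SDH1 fell (-0.50 ± 0.11 and -0.43 ± 0.11), 1 each way adjusted over the list alone. That list as a whole was upward, with vehicle 3 at -0.14 (mean 0.16; camera adjusted p = 0.0271, adjusted p = 0.521 with an estimated correlation). Without that array 0 of its genes rose and 0 fell.

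Of 36 sphingolipid genes 5 fell and 0 rose in SoyGC, and 10 fell and 1 rose adjusted over the list alone. They included the inositol phosphosphingolipid phospholipase ISC1 (-0.60 ± 0.14), the dehydratase PHS1 (-0.58 ± 0.14), the phosphatase YSR3 (-0.88 ± 0.22) and the hydroxylase SUR2 (-0.55 ± 0.14). The mean was -0.18 (95% interval -0.27 to -0.09; camera adjusted p = 0.0101, adjusted p = 0.458 with an estimated correlation), and -0.13 and -0.27 within the scan days. Vehicle 3 lay at 0.12 on this list, and without it 0 genes fell and the list had an adjusted p of 0.0684, in a range of 0.00279 to 0.128 over the alternatives. Of 28 ergosterol genes ERG24 (-0.52 ± 0.10), ERG4 (-0.53 ± 0.13) and HMG2 (-0.74 ± 0.15) fell, and 9 adjusted over the list alone (mean -0.22; camera adjusted p = 0.00304, adjusted p = 0.458 with an estimated correlation), and 0 fell without vehicle 3.

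Genes of the anaerobic and hypoxic cell surface, a list that includes sterol uptake, were lower: 11 of 30 fell and 1, CYC7, rose, with 17 and 1 adjusted over the list alone. DAN4 was at -1.38 ± 0.30, TIR3 at -0.95 ± 0.20 and HMG2 at -0.74 ± 0.15. The mean was -0.63 (95% interval -1.09 to -0.17; camera adjusted p = 4.2e-07, adjusted p = 0.43 with an estimated correlation), and -0.52 and -0.85 within the scan days. Vehicle 3 lay at 0.20 on this list, and 0 genes passed without it. Of 32 cell wall genes 6 fell, and 8 adjusted over the list alone, among them PST1 (-0.97 ± 0.13), the glucan synthase GSC2 (-0.51 ± 0.10) and TIP1 (-0.80 ± 0.16). Their mean was -0.21 (camera adjusted p = 0.000126, adjusted p = 0.271 with an estimated correlation), and 3 fell without vehicle 3. Of 26 pleiotropic drug resistance genes 8 fell, and 9 adjusted over the list alone, among them RTA1 (-0.64 ± 0.12), QDR3 (-0.58 ± 0.12) and TPO3 (-0.64 ± 0.13). Their mean was -0.31 (camera adjusted p = 0.00457, adjusted p = 0.252 with an estimated correlation), and 0 fell without vehicle 3.

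Of 34 autophagy genes 4 fell, also 4 adjusted over the list alone, among them the lipase ATG15 (-0.84 ± 0.12), ATG32 (-0.53 ± 0.10) and the vacuolar protease PRB1 (-0.60 ± 0.13). The mean was -0.21 (camera adjusted p = 0.00163, adjusted p = 0.252 with an estimated correlation), vehicle 3 lay at -0.28, and 2 fell without it. Of 21 thiamine genes THI4 (-0.75 ± 0.13) and THI2 (-0.47 ± 0.12) fell, and 5 adjusted over the list alone (mean -0.24; camera adjusted p = 0.00173, adjusted p = 0.252 with an estimated correlation). With vehicle 3 at -0.33 on the list and a mean of 0.041 without it, of 33 Hsf1 genes HSP26 rose (0.55 ± 0.12), also adjusted over the list alone as 1 gene (mean 0.15; camera adjusted p = 0.0271, adjusted p = 0.458 with an estimated correlation). Of 29 haploid-specific genes SAG1 (-0.78 ± 0.16) and MFA2 (-0.68 ± 0.17) fell, also 2 adjusted over the list alone (mean -0.18; camera adjusted p = 0.0271, adjusted p = 0.252 with an estimated correlation), and 1 fell without vehicle 3. The fusel alcohol list had 0 of 28 genes past the threshold and 0 adjusted over the list alone (mean -0.18; camera adjusted p = 0.0271, adjusted p = 0.458 with an estimated correlation).

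The general stress list moved both ways in SoyGC: 8 of 43 genes rose, including SOL4 (0.91 ± 0.14), NQM1 (0.55 ± 0.09) and OM45 (0.52 ± 0.09), and 6 fell, including the repressor XBP1 (-1.14 ± 0.15). Adjusted over the list alone 10 rose and 8 fell. The list did not pass camera (mean 0.10; adjusted p = 0.123, adjusted p = 0.583 with an estimated correlation), while fry's adjusted p for change in either direction was 9.9e-07. Without SoyGC 2 the mean was 0.030. Without vehicle 3, 6 rose and 2 fell. The list's adjusted p was 0.0286 without vehicle 3 and 0.0330 without SoyGC 3, in a range of 0.00362 to 0.547 over the alternatives, and with an estimated correlation it was 0.460 to 0.724 with each array left out.

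Of 34 lists 18 passed camera, 5 upward and 13 downward, and 0 with an estimated correlation. fry called 17 as moving one way on balance and 31 as changing in either direction. All 18 kept their sign within both scan days and 18 lists were called with scan day as a block. Most lists not called kept their sign as well, and the days split the values that gave the calls, so this tests little. The calls of the sphingolipid, Hsf1 and fusel alcohol lists were lost without vehicle 3. Those of the respiratory chain were lost without vehicle 1 or SoyGC 3, of Hsf1 also without SoyGC 2, of the fusel alcohol list also without SoyGC 3, and of haploid-specific genes without vehicle 1 or SoyGC 2. The normexp fit on median signals ended the respiratory chain and haploid-specific calls, and quantile normalization or only probes well above background on all 9 arrays the latter. Scan day 1 alone ended the sphingolipid, ergosterol, respiratory chain, Hsf1 and fusel alcohol calls, and array weights the ergosterol and trehalose calls. Of 1218 genes in the lists 154 passed, and this count was 109, 7 and 54 without vehicle 1, 2 and 3, 107, 91 and 95 without HenGC 1, 2 and 3, and 11, 24 and 0 without SoyGC 1, 2 and 3.

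The third comparison set the preparations against each other at the same dose, 40 ug/ml, and time, 17 h. MAL12 differed between HenGC and SoyGC by 0.07 (95% interval -0.32 to 0.47; adjusted p = 0.921), STR3 by 0.10 (-0.13 to 0.34; adjusted p = 0.761) and MEP1 by 0.14 (-0.21 to 0.50). These intervals bound the differences and do not show that the preparations act alike. The measured differences were larger for RGI2, 2.76 (95% interval 1.5 to 4.03), ADY2, 2.06 (1.07 to 3.04), POT1, 1.75 (0.97 to 2.53), and JEN1, 1.58 (0.78 to 2.38), all with less signal in SoyGC, but none passed after adjustment. All were among the genes named as lowest in SoyGC against vehicle, and the same SoyGC arrays enter here. Their differences may thus be overstated, and the 95% intervals do not allow for that choice. The smallest p-values were those of TDA1 (0.62 ± 0.10), GAC1, a regulator of glycogen synthesis (0.73 ± 0.13), and RMD5 (0.59 ± 0.11) on the HenGC side, and of the cyclin genes PCL1 (-0.64 ± 0.09) and CLB6 (-0.73 ± 0.11) and MF(ALPHA)2 (-0.75 ± 0.12) on the SoyGC side. Each had an adjusted p of 0.240, and over the alternatives these 6 genes ranged from 0.0347 to 1.00. RGI2 and POT1 are named because of their SoyGC results, after their values were seen.

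With limma 0 genes passed between HenGC and SoyGC, 738 had an unadjusted p under 0.05, where 290.7 would by chance, and the smallest adjusted p was 0.240. The groups did not overlap at 1250 genes, or 21.5%, where chance gives 10%. Array weights gave 23 genes and leaving out the filter on dim probes 1, and the count was 0 with every array left out in turn and with scan day or slide as a block. The F-test for any difference among the 3 groups passed 111 genes, 345 with scan day as a block and 0 with slide as a fixed block. That count was 24 without vehicle 1, 0 without vehicle 2, 47, 16 and 37 without HenGC 1, 2 and 3, and 9, 9 and 5 without SoyGC 1, 2 and 3. Without vehicle 3 it was 96.

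Lists were called between the preparations under the preset correlation, with 0 members past the threshold over all genes in any list. Another split of the same arrays called 19 lists, against 17 for the real split. The number of lists called therefore does not show that the preparations differ. The general stress list was higher in HenGC at 39 of 43 genes, 3 adjusted over the list alone (mean 0.34, 95% interval 0.18 to 0.49; camera adjusted p = 1.6e-10, adjusted p = 0.169 with an estimated correlation). Trehalose and glycogen genes were higher at 20 of 21, 8 adjusted over the list alone (mean 0.39, 0.20 to 0.58; camera adjusted p = 1.6e-10, adjusted p = 0.211 with an estimated correlation). The tricarboxylic acid list was higher at 27 of 31, 8 adjusted over the list alone (mean 0.40, 0.23 to 0.58; camera adjusted p = 1.7e-07, adjusted p = 0.169 with an estimated correlation), and the autophagy list at 30 of 34, 0 adjusted over the list alone (mean 0.27, 0.02 to 0.52; camera adjusted p = 2.9e-06, adjusted p = 0.169 with an estimated correlation). All 30 anaerobic genes had positive differences, 1 past the threshold adjusted over the list alone (mean 0.46, 95% interval -0.00024 to 0.92; camera adjusted p = 4.6e-09, adjusted p = 0.289 with an estimated correlation). Ribosome biogenesis was lower in HenGC at 94 of 95 genes, 0 adjusted over the list alone (mean -0.28, -0.87 to 0.31; camera adjusted p = 5.5e-14, adjusted p = 0.374 with an estimated correlation). Cytosolic ribosomal proteins were lower at 128 of 137, 0 adjusted over the list alone (mean -0.14, -0.28 to -0.0013; camera adjusted p = 1.8e-13, adjusted p = 0.302 with an estimated correlation). Genes of G1/S were lower at 29 of 39, 10 adjusted over the list alone (mean -0.20, -0.31 to -0.09; camera adjusted p = 2.7e-08, adjusted p = 0.169 with an estimated correlation). Within scan days 1 and 2 the means were 0.27 and 0.47 for general stress, 0.39 and 0.40 for trehalose, 0.31 and 0.59 for the tricarboxylic acid list, 0.36 and 0.66 for anaerobic genes, -0.18 and -0.49 for ribosome biogenesis and -0.19 and -0.22 for G1/S. The mean of cytosolic ribosomal proteins was -0.094 without HenGC 3 and that of ribosome biogenesis -0.18 without SoyGC 3. With an estimated correlation the general stress and autophagy lists had an adjusted p of 0.0398 without SoyGC 2, in a range of 0.0398 to 0.313 with each array left out.

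Further lists higher in HenGC were the respiratory chain (mean 0.14), peroxisome (0.28), glycolysis (0.14), nitrogen catabolite repression and permease (0.22), drug resistance (0.17), membrane flippase (0.17) and hexose transport (0.19) lists. The mean of the respiratory chain was 0.085 without HenGC 1 and 0.24 without HenGC 2, that of glycolysis 0.085 without SoyGC 3. Their camera adjusted p was 0.00031, 0.000394, 0.00372, 0.00939, 0.0216, 0.0294 and 0.0313, and their adjusted p = 0.355, 0.218, 0.512, 0.397, 0.218, 0.211 and 0.279 with an estimated correlation. G2/M and the phosphate regulon, at -0.070 without SoyGC 1, were lower (-0.078 and -0.11; camera adjusted p = 0.00251 and 0.00327, adjusted p = 0.279 and 0.355 with an estimated correlation). Adjusted over the list alone 3 peroxisome genes were higher and 0 genes passed in the other 8 of these lists. The sphingolipid list differed by 0.05 (95% interval -0.04 to 0.14; camera adjusted p = 0.687, adjusted p = 0.848 with an estimated correlation). Of 34 lists 17 passed camera, 12 upward and 5 downward, 0 with an estimated correlation (2 without SoyGC 2), 6 by fry one way and 8 either way. All 17 kept their sign in both scan days, and 17 were called with scan day as a block. Most lists not called kept their sign as well, and the days split the values that gave the calls, so this tests little. The glycolysis, hexose transport, drug resistance, nitrogen and flippase calls were lost without SoyGC 3, the hexose and drug resistance calls also without HenGC 1, the nitrogen and flippase calls without HenGC 3, and the flippase call without SoyGC 1. Slide as a fixed block ended the glycolysis, hexose and drug resistance calls, array weights the nitrogen and flippase calls, and scan day 1 alone the hexose, drug resistance, nitrogen and flippase calls.

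The responses to HenGC and SoyGC were also compared gene by gene. Of genes called in both, 28 were higher in both, MAL12, MAL32 and STR3 among them, where independent lists of 53 and 194 genes would share 1.77. Another 11 were lower in both, RCK1 and MEP1 among them, where independent lists of 16 and 345 would share 0.949, and 0 were called in opposite directions. Both comparisons use the same vehicle arrays, so the groups were simulated 100 times as unchanged against them. Simulated genes varied independently, so the simulated ranges are too narrow for genes that vary together. They cannot settle whether the response is shared. Lists of these sizes, taken by p, then shared 38.9 higher and 14.4 lower genes with the vehicle's own spread, and 29.2 and 12.2 with a pooled spread. At these list sizes the overlap is no larger than the shared arrays alone give. Calls in both comparisons numbered 39 against 0.54 simulated (highest 5). Unchanged groups give few calls in either comparison, so that contrast says nothing of overlap beyond the shared arrays. Of all genes 80.1% had the same sign against 70.3% simulated (highest 71.7%). The 3 vehicle arrays are too few to give each comparison 2 of its own, and all of the excess over independent lists may come from the shared controls. All 69 HenGC genes and 529 of 539 SoyGC genes had the same sign in the other comparison, where simulated lists had 66.0 and 485 with the vehicle's own spread (highest 69 and 502). Across 5814 genes, which are not independent replicates, the fold changes correlated at r = 0.794 (rho = 0.793). The simulations of unchanged groups gave r = 0.733 with the vehicle's own spread and 0.608 with a pooled spread. The covariance was 0.0968 against simulated values of 0.0382 and 0.0216. Without vehicle 3, r was 0.679 (simulated 0.294) and the covariance 0.0499 (simulated 0.00579). These simulated values take the vehicle's spread from the remaining vehicle arrays, which share a slide, so they may be too low.

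**Figure D2:**
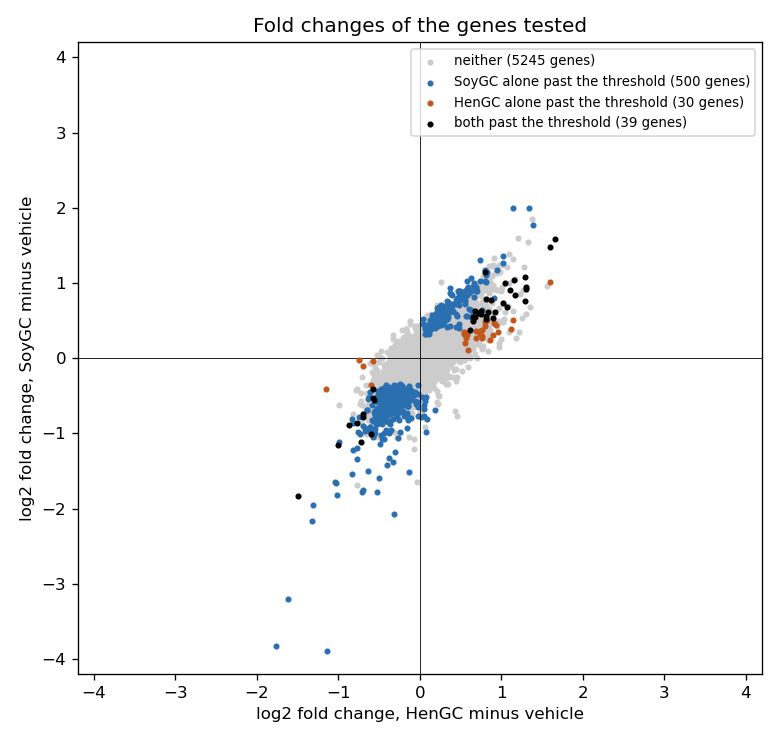
Log2 fold change of each of 5814 genes in HenGC (x axis) and SoyGC (y axis) against vehicle, coloured by the comparison in which a gene passed. Of the genes, 39 passed in both, 30 in HenGC alone, 500 in SoyGC alone and 5245 in neither, and passing in 1 comparison alone does not show a difference between the preparations.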

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

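The tests of explanations for the 3 patterns were chosen after the result was seen, except that the test of dim signals was set down before its own value was known. The counts over other splits of the arrays were planned.

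Vehicle 3 stood apart from vehicle 1 and 2 at 515 genes, and no biological explanation could be tested within a group. A shift of slide 3 or scan day 2 would move the treated arrays there too, but the slope of their deviations on that of vehicle 3 was 0.0348 for HenGC 3 and -0.263 for SoyGC 3. A treated culture under a vehicle label is argued against by the array's median position of 0.186 between vehicle (0) and HenGC (1), and -0.305 for SoyGC, and noisier spots by a ratio of spot variation to the other arrays of 1.05. A weaker response to dim signals stays open: 0.633 of the 515 genes were still over 2-fold off after quantile normalization, so a change of scale may account for some of them. What sets the rest apart was not settled.

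For the 12 genes lowest in SoyGC the median without vehicle 3 was 0.951 of that with it, and 5 of 12 passed without it. They were taken because every vehicle array lay above every SoyGC array. The other vehicle arrays thus had to differ too, and the share tests little. A shift shared by the arrays of a slide or scan day is argued against. Slides 1 and 3 each held both groups in equal numbers, so such a shift cancels. The median was -1.76 within slide 1 and -2.41 within slide 3. That the genes are lower within each slide follows from how they were taken, and an effect on single arrays was not tested. Lower expression of glucose-repressed genes is a hypothesis. For it, 8 genes of the glyoxylate cycle and gluconeogenesis were picked after some values were known. Their median was -0.79, with 6 of 8 lower, the fewest that the test asked for. Only ACS1 was past the threshold, and CAT8 was at 0.27. SFC1, among the 6 lower, was well above background on 1 SoyGC array only. All 8 belong to the tricarboxylic acid list, which was called lower in SoyGC from the same values, so the test adds little. Lower values of these genes may reflect more glucose left in the medium or an effect of SoyGC itself, and neither was tested. The MAL genes rose in the same SoyGC arrays (MAL12 by 1.59), and the hypothesis was not weighed against that rise.

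MAL12, MAL32, MAL31, MAL11 and STR3 were higher in both preparations, with MAL11 at 0.92 in HenGC and 0.62 in SoyGC. At least 0.992 of the mean difference stayed without vehicle 3. These genes passed in both comparisons with groups that do not overlap, so the other vehicle arrays had to differ too. The share therefore tests little. Shared signal between MAL12 and MAL32 cannot be told apart from a rise of both, as their changes differed by at most 0.108. A maltose-like sugar in both preparations stays open: MAL12 differed between them by 0.0735 (95% interval -0.32 to 0.47), and MAL11 was higher in HenGC by 0.30 (0.03 to 0.57; adjusted p = 0.369). An effect of the preparations themselves was not tested.

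With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 69 genes for HenGC against a highest other of 1, in 1 of 10 splits as large, 539 for SoyGC against 0, in 1 of 10, and 0 between the preparations against 0, in 10 of 10. For lists the real splits gave 16, 18 and 17 against a highest other of 16, 17 and 19, with 2, 1 and 2 of 10 as large. Counts of lists close to the real ones thus also came from other splits. For the F-test, 1 of 100 splits drawn of the 280 possible, the real one, gave as many as 111 genes, a share under 0.05. That would exclude chance only if the arrays could be exchanged freely. Slide 2 held HenGC arrays alone, so they cannot, and chance is not excluded. The splits did not keep slides apart, and the count was 0 with slide as a fixed block. It was 24, 0 and 96 without vehicle 1, 2 and 3, 47, 16 and 37 without HenGC 1, 2 and 3, and 9, 9 and 5 without SoyGC 1, 2 and 3. The highest other gave 95 and kept the 3 vehicle arrays together.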

How the results depend on the processing

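Alternatives that use scan day, member counts without vehicle 3, and estimated correlations with an array left out were chosen after seeing the data; the others were planned, normexp on mean signals and run on median ones.

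The 69 HenGC genes became 39 with quantile normalization, 26 with median scaling, 3 in the authors' unscaled table, 45 without the dim filter, 0 with slide as a fixed block, 6 with only these groups, 862 with array weights, 125 with scan day as a block and 18 at 2-fold, and 3 to 50 with each array left out. The 539 SoyGC genes became 315 with median scaling, 8 in the authors' table, 188 with slide fixed, 50 with only these groups, 1246 with array weights, 35 on scan day 1 alone, 39 within slide 1, 58 at 2-fold and 2 to 387 with each array left out. The 0 genes between preparations became 1 without the dim filter and 23 with array weights, and stayed 0 to 0 with arrays left out. The F-test's 111 became 56 with median scaling, 5 in the authors' table, 0 with slide fixed, 1335 with array weights, 345 with scan day as a block, 25 on scan day 1 and 0 to 96 with arrays left out. The correlation of 0.794 became 0.731 with slide fixed, 0.662 on scan day 1 and 0.679 to 0.860 with arrays left out. Fits with fewer arrays or groups have fewer degrees of freedom, and for the others the cause was not tested. The weights' iterations warned that they had not converged. The authors' table shifted the median of all genes in HenGC by -0.148.

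Counts of lists kept within 1.5 times: 13 to 19, 16 to 20 and 12 to 21 with arrays left out. With an estimated correlation the 0 lists became 2 without SoyGC 2 between the preparations and stayed 0 otherwise. Of the lists called, 10 of 16, 11 of 18 and 12 of 17 were called in all 24 alternatives. Cytosolic ribosomal proteins in HenGC had a mean of 0.0063, with 0 of 137 genes past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.947). They turned to an upward call with means of 0.062 after quantile normalization and 0.042 on scan day 1. The smallest camera adjusted p over the alternatives, 0.00758, belonged to a downward call, so the list was called in both directions. The cause was not tested.

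For genes taken by the naming rule, an alternative changed no call in 2969 cases for HenGC, with 419 calls lost and 114 gained, in 2521 for SoyGC, with 1004 lost and 96 gained, and in 3133 between the preparations, with 0 lost and 10 gained.

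The replicate numbers were not taken to pair the samples, although number 3 shares a slide and a scan day: same-numbered arrays' deviations correlated at -0.647 to 0.558, and 6 of 9 arrays were closest to one of their own number. With the replicate block 86, 587 and 0 genes, 307 by the F-test and 17, 19 and 17 lists passed.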

Other observations

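The tests of other lists were planned, and the test of the cell cycle hypothesis was chosen after the result was seen.

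Of 28 iron regulon genes 5 rose and 1 fell in SoyGC, and the list did not pass. Those that rose include the scaffold gene ISU2 (0.89 ± 0.16), the reductases FRE1 (0.67 ± 0.15) and FRE4 (0.51 ± 0.12) and the permease FTR1 (0.52 ± 0.12), with 5 and 3 adjusted over the list alone (camera adjusted p = 0.138). In HenGC 0 passed, 2 adjusted over the list alone (0.622). Without vehicle 3, 2 rose and 0 fell in SoyGC. The list had an adjusted p of 0.0367 without vehicle 3 and 0.0114 without SoyGC 2 (range over the alternatives 0.0114 to 0.593), and 0.479 to 0.766 with an estimated correlation and each array left out. Of 34 sulfur and methionine genes, STR3, the regulator MET28 (0.75 ± 0.13) and the permease MUP3 (0.82 ± 0.15) rose in HenGC, 4 adjusted over the list alone (camera adjusted p = 0.216, 0.0254 without vehicle 3 and 0.00591 without HenGC 1, in a range of 0.00591 to 0.555, and 0.526 to 0.878 with an estimated correlation and each array left out). In SoyGC 3 rose and 2 fell, 5 and 4 adjusted over the list alone (0.665), and 2 and 0 without vehicle 3. Of 30 peroxisome genes 4 fell and 1 rose in SoyGC, 7 and 1 adjusted over the list alone, among them POT1, the acyl-CoA oxidase POX1 (-1.24 ± 0.29) and TES1 (-0.67 ± 0.14), with PEX21 rising (0.64 ± 0.16; camera adjusted p = 0.0898). Without vehicle 3, 1 fell and 0 rose, and without HenGC 1 the list had an adjusted p of 0.0449 (range 0.0285 to 0.134; 0.267 to 0.589 with an estimated correlation and each array left out). In HenGC 0 passed, 1 adjusted over the list alone (0.563).

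Of 29 membrane flippase and eisosome genes DNF2 (-0.51 ± 0.11), NEO1 (-0.58 ± 0.13) and FMP45 (-0.63 ± 0.17) fell in SoyGC, also 3 adjusted over the list alone (camera adjusted p = 0.0621). Without vehicle 3, 0 fell. The list had an adjusted p of 0.0337 without vehicle 3, 0.0388 without HenGC 1 and 0.0272 without SoyGC 2 (range over the alternatives 0.0272 to 0.162), and 0.242 to 0.470 with an estimated correlation and each array left out. In HenGC 0 passed, 1 adjusted over the list alone (0.735). Of 30 fatty acid and phospholipid genes the repressor OPI1 (0.58 ± 0.11) and CDS1 (0.41 ± 0.11) rose and PIS1 fell (-0.49 ± 0.12) in SoyGC, 2 and 2 adjusted over the list alone (0.318), 0 and 1 without vehicle 3, and 0 passed in HenGC over all genes or adjusted over the list alone (0.16). Of 23 zinc and copper genes VEL1 (-0.74 ± 0.13), ZPS1 (-0.62 ± 0.13) and ZRG8 (-0.59 ± 0.13) fell and FRE1 rose in SoyGC, 3 and 1 adjusted over the list alone (0.272) and 1 and 0 without vehicle 3. VEL1 fell in HenGC, also 1 adjusted over the list alone (0.473), and 0 without vehicle 3. Of 35 Yap1 genes MXR1 (0.63 ± 0.12), PRX1 (0.50 ± 0.11) and GPX2 rose in SoyGC, also 3 adjusted over the list alone (0.0925). Without vehicle 3, 2 rose and the list had an adjusted p of 0.00872 (range 0.00309 to 0.308), and 0.407 with an estimated correlation.

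Single genes passed in lists that did not. In SoyGC the Gcn4 list of 51 genes had GCV1 higher (0.65 ± 0.17) and GDH1 lower (-0.43 ± 0.09), 0 adjusted over the list alone (0.626), the alkaline pH list of 38 genes ENB1 higher (0.54 ± 0.13), 0 adjusted over the list alone (0.123), and the hexose transport list of 17 HXT9 lower (-0.57 ± 0.13), 1 adjusted over the list alone (0.629). PHM8 was lower in the phosphate list of 24 (-0.85 ± 0.18; 0.446), RNR3 in the G1/S list of 39 (-0.82 ± 0.19; 0.419), BUB2 in the G2/M list of 34 (-0.48 ± 0.11; 0.899) and GSC2 in the meiosis list of 29 (-0.51 ± 0.10; 0.906), where 1, 0, 0 and 1 genes were lower adjusted over the list alone. Without vehicle 3, 0 genes passed in the Gcn4, alkaline pH, hexose transport, G1/S and G2/M lists in SoyGC. In HenGC MTH1 rose in the hexose transport list (0.69 ± 0.12; 0.444), GIP2 in the trehalose list (0.96 ± 0.19; 0.16) and CYC7 in the anaerobic list (0.115), while CAT8 rose (0.77 ± 0.14) and CIT2 fell in the tricarboxylic acid list (0.622). Adjusted over the list alone, 2 hexose transport, 1 trehalose and 1 anaerobic gene rose, and 1 tricarboxylic acid gene rose and 4 fell. Without vehicle 3, 0 genes passed in the hexose transport, trehalose and tricarboxylic acid lists in HenGC. The unfolded protein response list of 31 genes had 0 past the threshold in both (0.0643 and 0.626), and in HenGC the Gcn4 (0.109), alkaline pH (0.585), meiosis (0.444), glycolysis (0.093), drug resistance (0.115) and autophagy (0.857) lists had 0. Adjusted over the list alone 2 alkaline pH genes rose, 1 meiosis gene rose and 2 fell, and 0 passed in the others. Values in brackets without a sign of error are camera adjusted p. Without vehicle 3 the unfolded protein and trehalose lists had an adjusted p of 0.0112 and 0.0074 in HenGC (ranges 0.00952 to 0.237 and 0.00307 to 0.856), and 0.189 and 0.498 with an estimated correlation. Without HenGC 2 that of the unfolded protein list was 0.0491 (0.278 with an estimated correlation). In HenGC the adjusted p was 0.0417, 0.0350 and 0.0331 for glycolysis without vehicle 1, HenGC 1 and HenGC 2 (range 0.00425 to 0.969), and 0.0355 and 0.0350 for Gcn4 without vehicle 1 and HenGC 1 (0.00425 to 0.969). It was 0.0468 and 0.00533 for the anaerobic list without vehicle 1 and HenGC 2 (0.00533 to 0.876), and 0.0338 for drug resistance without HenGC 1 (0.0338 to 0.327). With an estimated correlation 0 lists passed in HenGC with any array left out. The meiosis list lay at -0.54 in vehicle 3 relative to vehicle 1 and 2.

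In 12 list results, 0 of them past the threshold, the median, the mean and camera's direction differed in sign: iron, cytosolic ribosomal, flippase and autophagy lists in HenGC, unfolded protein, sulfur, G2/M and meiosis lists in SoyGC, and fatty acid, Yap1, mitochondrial ribosomal and haploid-specific lists between the preparations.

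Fewer HenGC cells in late G1 and S phase than SoyGC cells is a hypothesis that these data leave open. The G1/S list prompted it, and the list's mean difference of -0.194 in scan day 1 and -0.218 in scan day 2 splits the same values, so it tests nothing further. PCL1 (-0.64 ± 0.09), CLB6 (-0.73 ± 0.11), CDC45 (-0.48 ± 0.09) and POL12 (-0.51 ± 0.11) were lowest in p. The list's adjusted p was 0.169 with an estimated correlation, G2/M genes were lower too (-0.078), and no cell counts were analysed here.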
